A study of Homo sapiens with 6 samples.

How the data were processed

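RNA was sequenced from cells of the human induced pluripotent stem cell (iPSC) line CRL1502, clone C32, at the start of a kidney differentiation protocol. Per the labels, 3 libraries came from undifferentiated cells kept in medium conditioned by mouse embryonic fibroblasts (day 0), and 3 came from cells at the late primitive streak stage (day 4) after culture with 8 uM CHIR99021 in APEL medium. CHIR99021 inhibits the kinase GSK3 and so activates Wnt and beta-catenin signalling. The labels do not say whether libraries of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. Total RNA was extracted with a column kit for small samples and libraries were prepared by Illumina's usual protocols, per the labels. Whether ribosomal RNA was depleted or polyadenylated RNA was selected is not given in the sources used here.

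The values are the raw read counts per gene symbol that the authors deposited, made with STAR 2.4.0h1 and featureCounts 1.4.6 on the hg19 genome build per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited table also gives a length in bp for each symbol, per the file headers, which was used only to look at how symbols with several annotated copies were counted. The table lists 42785 gene symbols, of which 30776 had at least 1 count, and 0 of its value columns belonged to no known sample. It holds 0 entries that name no gene. Genes that share a symbol are merged in it. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and near-identical copies can share reads. Total counts per library were 19486135, 23606387 and 26679897 at day 0 and 28556272, 19223292 and 23264420 at day 4, so depth did not separate the groups.

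Samples were grouped by the day in their labels. The tests, gene lists, rule for named genes and alternatives given here were fixed before the data were examined, except where stated. XIST, TSIX and genes with Y-linked names (152 symbols) were left out of all tests and kept in the library totals. Genes were filtered with filterByExpr at its default settings, which left 16806, and libraries were scaled by the trimmed mean of M-values (TMM). Day 4 was compared with day 0 by edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of genes come from that test. A second test on the same fit (glmTreat) asked for a change beyond 2-fold, a log2 fold change of 1. Levels are TMM-scaled CPM (counts scaled to a common library total), given as mean ± SD of 3 libraries, and log2 fold changes are day 4 over day 0 with their standard error (SE). Where a group had 0 counts in all its libraries, the fold is a lower bound against 3 counts over that group. Where it had 1 to 3 counts in all, the fold is the ratio with its 95% counting interval, and no fold is given where both groups were at or under 3 counts. Bounds and intervals cover counting error only.

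The 31 gene lists came from textbook knowledge. They cover pluripotency, the primitive streak, caudal and neuromesodermal progenitors, presomitic mesoderm, intermediate mesoderm, lateral plate mesoderm, blood and endothelium, definitive endoderm, node and notochord, neural ectoderm, surface ectoderm with amnion and trophoblast, fibroblasts, primordial germ cells, the Wnt, FGF, Nodal, BMP, Notch and retinoic acid pathways, HOX genes in 3 groups, epithelial junctions, mesenchymal transition, mitosis, DNA replication, p53 targets, cholesterol synthesis, glycolysis, oxidative phosphorylation from the mitochondrial genome, and immediate early with heat shock genes. Each list with at least 3 tested members (30 of the 31) was tested against all other genes with camera at a preset correlation between genes of 0.01, two-sided, and adjusted over the lists by Benjamini-Hochberg. Some genes are members of several lists.

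The rule for genes named in the text takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 10 CPM in the higher group and no overlap between groups. It adds a fixed set of 24 marker genes whatever their values. From each list it takes up to 4 passing members with the largest change and at least 1 CPM in the higher group, and up to 2 members that did not pass, those with the highest mean CPM. Genes named outside that rule are said to be chosen after their values were seen, and some genes that the rule takes are not reported here. Gene symbols were matched to GENCODE v29 (27798 matched), which was used for names, gene classes and neighbouring genes only, since it is built on another genome assembly than hg19.

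The test was checked on simulated counts for 16806 genes drawn from the means and library sizes of these libraries. It recovered 63.2% of 57 genes changed by 1.5-fold, 76.4% of 72 changed by 2-fold and 97.2% of 71 changed by 4-fold, and 5.33% of its calls were false. All other simulated genes were unchanged, whereas 76.9% of genes changed between these stages. Recovery, false calls and scaling depend on that share, so these values do not carry over to the comparison itself. In a separate simulation of the same kind camera called the 1 changed list and 0 of the other lists, 30 in all. Genes were drawn independently there, so it does not check camera where genes of a list vary together. Alternatives were relative log expression, upper quartile or no scaling factors, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, removal of mitochondrial genes, each library left out in turn, camera with a correlation estimated per list, and the rotation test fry. Removal of ribosomal and other structural RNA genes was added after seeing the data. Figures were drawn with matplotlib 3.10.9.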

Results

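Gene expression was measured by RNA sequencing in undifferentiated human iPSCs (day 0, n = 3) and in the same line after 4 days with 8 uM CHIR99021 (day 4, n = 3), the first stage of a protocol that leads to kidney cells. Library totals ranged from 19223292 to 28556272 counts. The comparison asks which genes set the late primitive streak stage apart from the undifferentiated stage. Culture medium, CHIR99021 and time differ together between the groups, and no day 4 group without CHIR99021 was sequenced. Their effects on any gene or list below cannot be told apart. Across genes, the correlation of log CPM was 0.9947 to 0.9958 between day 0 libraries, 0.9892 to 0.9947 between day 4 libraries and 0.7922 to 0.8004 between the stages, where genes are not independent replicates. No pair of libraries differed by as little as sampling noise, since chi-square over degrees of freedom was at least 3.76 within day 0 and at least 18.9 within day 4. The first principal component held 95.7% of the variance and the second 1.99%.

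By day 4 the cells had lost NANOG and SOX2, transcription factors of the pluripotent state, and had gained the primitive streak factors T and MIXL1, the caudal factors CDX1 and CDX2 and HOX genes of paralogue groups 1 to 9. SOX2 fell from 279 ± 6.19 to 0.21 ± 0.11 CPM, and T rose from 0.193 ± 0.122 to 55.3 ± 3.6 CPM (SD, n = 3 each). Negative feedback genes of the Wnt pathway were among the strongest rises, with DKK1 at 2301 ± 507 CPM at day 4 against 0.141 ± 0.0451 at day 0. Among members of the Nodal list 10 of 11 fell, and of the epithelial list 13 of 16 fell and 3 rose (adjusted p = 0.0543 and adjusted p = 0.0616 with an estimated correlation). Of 16806 genes tested, 12928 (76.9%) changed, 6499 upward and 6429 downward, and 5096 (30.3%) changed by more than 2-fold, 2415 upward and 2681 downward. CPM did not overlap between the groups for 79.8% of tested genes, where chance gives 10%.

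Of the 30 lists tested, 21 were called, 13 upward and 8 downward, and 6 of these calls held with a correlation estimated per list. Those 6 were pluripotency, primitive streak, caudal and neuromesodermal progenitors, Wnt feedback targets, HOX groups 1 to 4 and mesenchymal transition. When the 6 libraries were regrouped across stages, camera at the preset correlation still called 7 to 15 lists, and with an estimated correlation it called 0. Each regrouped set still held unequal numbers of day 0 and day 4 libraries, so neither number is a chance level. Counts of members adjusted over the list alone were equal to those over all genes tested, except in the 3 lists where both are given. Cytoplasmic 28S ribosomal RNA took 1.88%, 1.78% and 2.4% of counts at day 0 and 3.45%, 8.89% and 2.35% at day 4. Small structural RNAs (RMRP, RN7SK, RN7SL1, RN7SL2 and RPPH1) took 1.33% to 1.92% at day 0 and 3.36% to 3.8% at day 4.

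**Figure D1:**
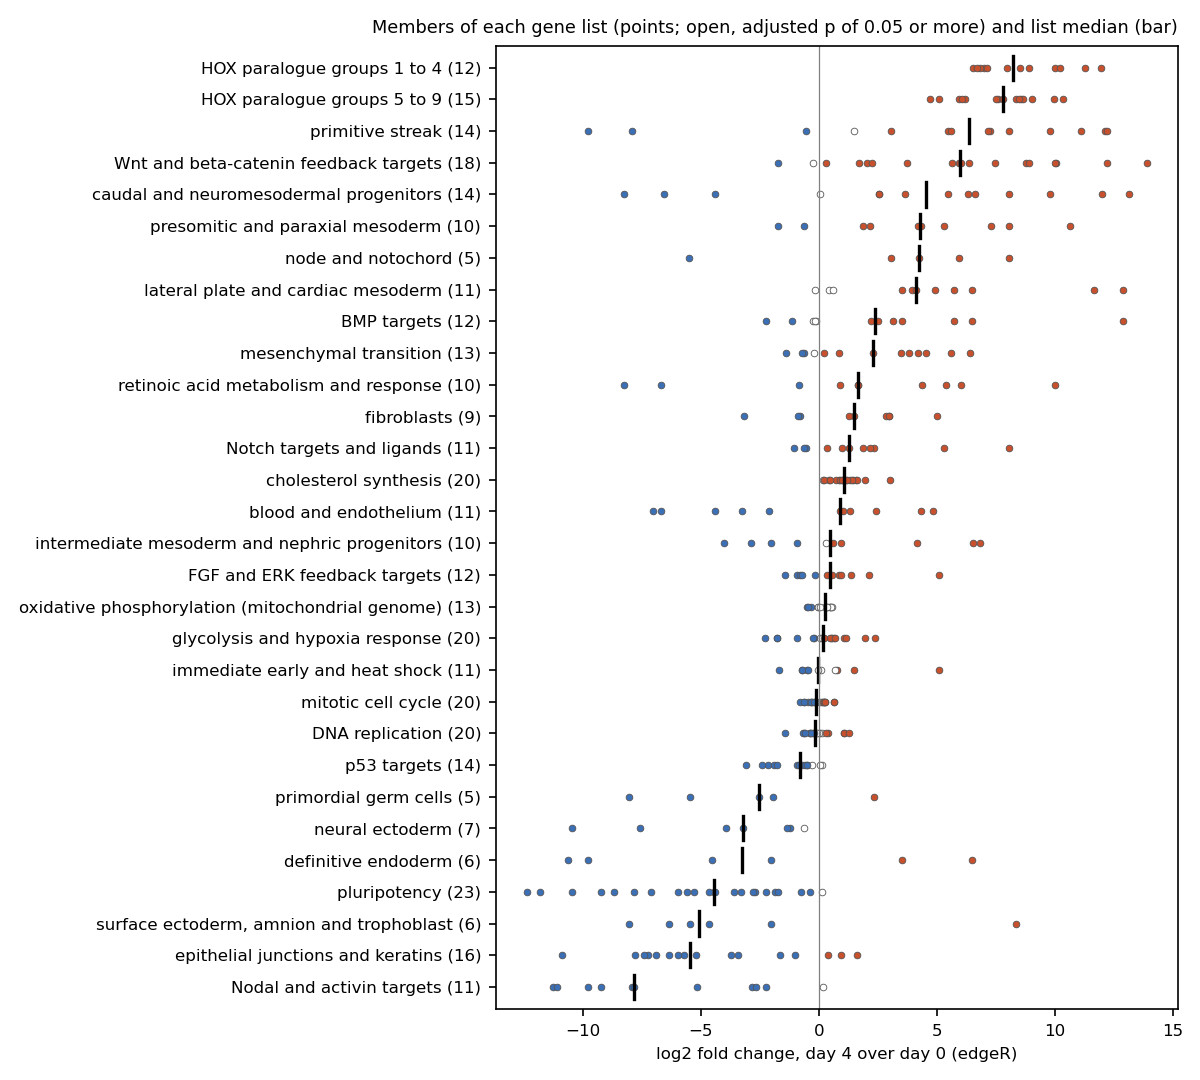
Members of each gene list by log2 fold change of day 4 over day 0 (horizontal axis, edgeR), with lists ordered by their median (black bar) and the number of tested members in brackets. Filled points passed the test (orange rose, blue fell), open points did not, genes with 0 counts in a group are drawn at a fitted value that is not a bound, and medians run from -7.81 (Nodal) to 8.24 (HOX groups 1 to 4).

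The 10 strongest rises by fitted fold change were RP11-834C11.3, HOXA-AS3, HOXB-AS3, DKK1, URAD, AC007277.3, CDX1, MSX1, MYH6 and TRDC. RP11-834C11.3, an uncharacterised transcript, was at least 2784-fold higher at day 4 (124 ± 16.3 CPM), and HOXA-AS3, an antisense transcript in the HOXA cluster, at least 2191-fold higher (95.6 ± 2.27 CPM). Both had 0 counts at day 0. HOXB-AS3 had 1 count at day 0 and 317 ± 14.8 CPM at day 4, 21660-fold higher (95% counting interval 3887 to 855600). URAD, which lies next to CDX2, was at least 1475-fold higher and AC007277.3 at least 1330-fold higher. MSX1, a homeobox target of BMP signalling, was 8335-fold higher (95% counting interval 2852 to 40420), and MYH6, a cardiac myosin heavy chain, 6230-fold higher (1724 to 51450). TRDC, the constant segment of the T cell receptor delta chain, was at least 598-fold higher at 26.7 ± 8.02 CPM. The 10 strongest falls by fitted fold change were those of IDO1, NANOG, HHLA1, LINC00678, PRDM14, RP4-792G4.2, TRBC2, NLRP7, AADACL3 and CTC-286N12.1. In both rankings the fitted value of a gene with 0 counts in a group is no bound, so its rank is uncertain. IDO1, which degrades tryptophan, fell from 29.2 ± 0.55 CPM to 0 counts, at least 704-fold. HHLA1 was 5254-fold lower (1797 to 25480) and LINC00678 6298-fold lower (1130 to 248800). TRBC2 (at least 427-fold), NLRP7 (at least 403-fold) and CTC-286N12.1 (at least 387-fold) also fell to 0 counts. RP4-792G4.2 was 4759-fold lower (854 to 188000) and AADACL3 3694-fold lower (1022 to 30510). The adjusted p of these 20 genes was at most 3.9e-07.

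Pluripotency genes fell together. Of 23 tested members 22 fell, 0 rose and 1 did not pass (camera adjusted p = 3.2e-31, and adjusted p = 0.0181 with an estimated correlation). NANOG was 7328-fold lower (1315 to 289500) and PRDM14, a repressor that guards the pluripotent state, 4030-fold lower (1379 to 19540). TDGF1, a co-receptor for Nodal, fell by 9.23 ± 0.24 (SE) on the log2 scale, and the log2 fold change was -10.14 without day 4 replicate 1. LIN28B did not pass (380.5 ± 12.2 and 414 ± 37.9 CPM, adjusted p = 0.139), though its adjusted p ran from 0.0164 to 0.445 over the alternatives and passed with upper quartile factors and without day 4 replicate 2 (0.0168). POU5F1, which encodes OCT4, was not tested, because the table lists only 1, 1 and 2 counts at day 0 and 0 counts in each day 4 library. In the genomic region around it, 73.1% of 145 protein-coding genes had under 10 counts, so no level is read from it.

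Targets of Nodal and activin fell, with 10 of 11 tested members lower, 0 higher and 1 not passing (camera adjusted p = 2.5e-18, but adjusted p = 0.0543 with an estimated correlation). LEFTY1 and LEFTY2, secreted inhibitors of Nodal, fell from 148 ± 1.89 and 221 ± 10 CPM, with log2 fold changes of -11.26 ± 0.12 and -11.08 ± 0.14 (SE). CER1, another inhibitor of Nodal, had 53.2 ± 2.44 CPM at day 0 and 4 counts in all at day 4.

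Primitive streak genes rose in 10 of 14 tested members, fell in 3 and did not pass in 1, and adjusted over the list alone 11 rose and 3 fell (camera adjusted p = 8.1e-11, and adjusted p = 0.0387 with an estimated correlation). MIXL1 rose 152-fold to 149 ± 0.665 CPM, and T, the Brachyury factor, 265-fold. SP5 rose by 12.20 ± 0.19 (SE) on the log2 scale to 300.1 ± 23.1 CPM, and by 11.55 without day 0 replicate 3. FGF17 was 4951-fold higher (1694 to 24010), the apelin receptor APLNR 2697-fold higher (746 to 22280) and EVX1 1220-fold higher (219 to 48210). The 3 members that fell were CER1, the ligand NODAL (57.5 ± 2.19 to 0.228 ± 0.0715 CPM) and WNT3 (8.82 ± 0.447 to 6.09 ± 0.773 CPM), the last 2 named after their values were seen. MESP1 did not pass (0.222 ± 0.28 and 0.729 ± 0.266 CPM, adjusted p = 0.0588), and its adjusted p ran from 0.00177 to 0.177 over 15 alternatives, of which 6 passed, among them those without day 0 replicate 3 (0.00519) and without day 4 replicate 1 (0.0026). EOMES, a factor of the early streak, was too low for the test, with 4, 8 and 5 counts at day 0 and 1, 1 and 0 at day 4.

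Caudal and neuromesodermal progenitor genes rose in 10 of 14 members, fell in 3 and did not pass in 1 (camera adjusted p = 4.6e-07, and adjusted p = 0.0387 with an estimated correlation). CDX1 was 10150-fold higher at day 4 (3473 to 49230), at 445 ± 8.82 CPM, and CDX2 4578-fold higher (1566 to 22200), at 201 ± 7.21 CPM. CYP26A1, which breaks down retinoic acid, went the other way, from 146 ± 7.26 to 0.506 ± 0.265 CPM. The other members that fell, named after their values were seen, were NKX1-2 (8.19 ± 0.343 to 0.0798 ± 0.11 CPM) and GRHL3 (5.91 ± 0.55 to 0.284 ± 0.0857 CPM). TLX2 did not pass (0.657 ± 0.104 and 0.7 ± 0.262 CPM, adjusted p = 0.928).

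**Figure D2:**
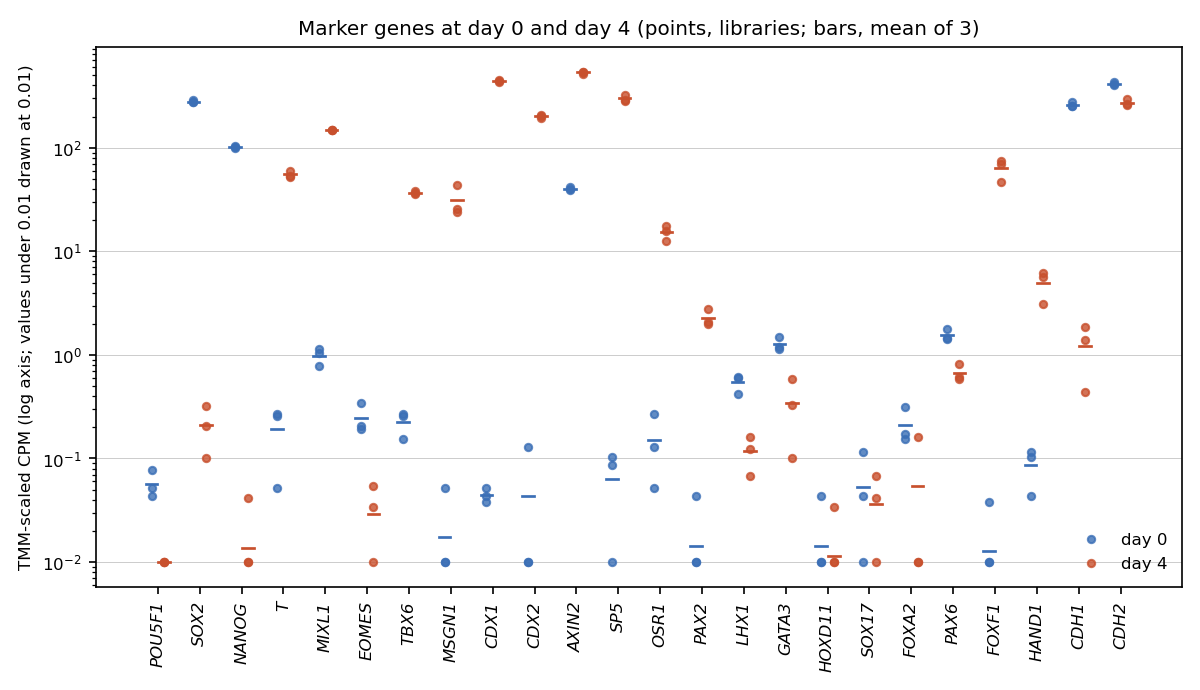
The 24 marker genes as TMM-scaled CPM on a log axis, with 1 point per library, bars for the mean of 3 libraries, and values under 0.01 drawn at 0.01. Mean levels of SOX2, NANOG and CDH1 are 279, 101 and 260.5 CPM at day 0 and 0.21, 0.0137 and 1.23 CPM at day 4, while CDX1, AXIN2 and SP5 have means of 445, 534 and 300.1 CPM at day 4.

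Presomitic and paraxial mesoderm genes rose in 8 of 10 tested members and fell in 2 (camera adjusted p = 0.00039, but adjusted p = 0.118 with an estimated correlation). TBX6, a master regulator of this lineage, rose 155-fold to 37 ± 0.952 CPM. MSGN1 was 2247-fold higher (403 to 88790), at 31.2 ± 11.2 CPM, and HES7 and DLL1, of the segmentation clock, rose by 8.04 ± 0.43 and 5.28 ± 0.42 (SE) on the log2 scale. HES7 had only 4 counts at day 0 and rose by 9.36 without day 0 replicate 1 and by 7.38 without day 0 replicate 3. Day 4 replicate 1 stood apart in this list, with a median deviation of 0.543 (log2) from the other day 4 libraries, and DLL1 was at 116, 41.9 and 54.1 CPM in the 3 day 4 libraries. Notch targets and ligands rose in 8 of 11 tested members and fell in 3 (camera adjusted p = 0.0353, but adjusted p = 0.516 with an estimated correlation). Of its members, HES7, DLL1, DLL3 and LFNG are shared with the presomitic list. The 3 that fell, named after their values were seen, were the Notch targets HEY1, HEY2 and NRARP, with log2 fold changes of -0.54, -0.64 and -1.05. In the Notch list DLL3 rose by 2.17 ± 0.12 (SE) and HEYL by 2.33 ± 0.43 on the log2 scale, and HEYL rose by 1.69 without day 4 replicate 1. The same library deviated by 0.647 in the Notch list.

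Lateral plate and cardiac mesoderm genes rose in 8 of 11 tested members, fell in 0 and did not pass in 3 (camera adjusted p = 7.4e-07, but adjusted p = 0.118 with an estimated correlation). FOXF1 was 4235-fold higher (760 to 167300), at 63.7 ± 14.6 CPM. MSX2 rose 89.1-fold to 139 ± 3.91 CPM, and HAND1 53.5-fold to 5 ± 1.65 CPM. BMP4 did not pass at 21.9 ± 1.32 and 19.2 ± 2.87 CPM (adjusted p = 0.159), and over the alternatives its adjusted p ran from 0.00107, without day 4 replicate 1, to 0.489. In this list the median deviation of day 4 replicate 1 was -0.617. BMP targets, which share MSX1, MSX2, HAND1 and BMP4 with that list, rose in 7 of 12 members, fell in 2 and did not pass in 3 (camera adjusted p = 0.00064, but adjusted p = 0.128 with an estimated correlation). ID2, a direct BMP target, rose by 3.51 ± 0.15 (SE) on the log2 scale. Its relative ID1 did not pass (194 ± 6.78 and 177 ± 14.1 CPM, adjusted p = 0.0942), and was called lower without day 4 replicate 1 (0.000286). The 2 members that fell, named after their values were seen, were ID4 and SMAD7, with log2 fold changes of -1.13 and -2.24.

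Intermediate mesoderm and nephric progenitor genes, which mark the tissue that forms the kidney, rose in 5 of 10 tested members, fell in 4 and did not pass in 1. The list did not differ from other genes by camera (adjusted p = 0.251), while fry, which makes no comparison with other genes, called it upward (0.00582). OSR1 rose 92.1-fold from 0.15 ± 0.11 to 15.3 ± 2.58 CPM, a log2 fold change of 6.53, or 7.25 without day 0 replicate 3. PAX2 was 154-fold higher (27.2 to 6101), but only at 2.3 ± 0.43 CPM. SALL1 rose by 4.13 ± 0.12 (SE) on the log2 scale to 173 ± 23.9 CPM. GATA3 fell by 2.03 ± 0.42 and RET, a receptor of the ureteric bud, by 2.87 ± 0.43 (SE) on the log2 scale. RET fell by 2.27 without day 4 replicate 1. LHX1 was too low for the test, with 8, 14 and 16 counts at day 0 and 2, 3 and 3 at day 4.

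All 12 members of HOX paralogue groups 1 to 4 and all 15 members of groups 5 to 9 rose. Camera gave an adjusted p of 5.2e-13 for the first list (adjusted p = 0.0387 with an estimated correlation) and 6.5e-15 for the second (adjusted p = 0.0543 with an estimated correlation). Median log2 fold changes were 8.24 and 7.8, or 7.61 and 7.48 with genes at 0 counts set to their bound. HOXD3 and HOXA3 were at least 495-fold and at least 302-fold higher, and HOXC4 was 1320-fold higher (451 to 6404). HOXB9 rose 1311-fold to 198 ± 29.1 CPM and HOXB7 516-fold to 77.9 ± 1.72 CPM. HOXC5 and HOXA6 were at least 122-fold and at least 48.6-fold higher. None of the 12 members of groups 10 to 13 had enough counts for the test, and their day 4 means were at 0.595 CPM or lower. Named after their values were seen, HOXA10 went from 1 to 44 counts in all (41.7-fold, 7.1 to 1684), HOXB13 from 1 to 23 (21.8-fold, 3.54 to 898) and HOXD13 from 2 to 18 (8.53-fold, 2.04 to 75.8). HOXD11, a marker of later kidney mesenchyme, had 1 count in all at each stage.

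Retinoic acid genes rose in 7 of 10 tested members and fell in 3, without a call for the list (camera adjusted p = 0.136, 0.00822 without day 4 replicate 1 and 0.00235 to 0.479 over the alternatives). ALDH1A2, which makes retinoic acid, rose by 6.02 ± 0.22 (SE) on the log2 scale to 14.6 ± 1.19 CPM. CRABP1, which binds it, fell by 6.68 ± 0.12.

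Wnt and beta-catenin feedback targets rose in 16 of 18 members, fell in 1 and did not pass in 1 (camera adjusted p = 5e-28, and adjusted p = 0.0181 with an estimated correlation). AXIN2, a negative regulator induced by the pathway, rose 13.3-fold from 40.3 ± 1.13 to 534 ± 16.5 CPM. DKK1, a secreted Wnt antagonist, rose by 13.90 ± 0.27, NKD1 by 10.05 ± 0.13 and NOTUM, an enzyme that inactivates Wnt proteins, by 10.01 ± 0.11 (SE) on the log2 scale. The member that fell was MYC (121 ± 6.01 to 35.8 ± 10.7 CPM), a growth regulator named here after its values were seen. BAMBI did not pass (75.1 ± 2.98 and 63.1 ± 12.8 CPM, adjusted p = 0.0875), though its adjusted p ran from 0.000688 to 0.25 over the alternatives and it passed with no filter, with DESeq2 and without day 4 replicate 2 (0.0361). Feedback targets of FGF and ERK signalling were mixed, with 7 higher and 5 lower of 12 (camera adjusted p = 0.231). EGR1 rose by 5.07 ± 0.19 and the phosphatase DUSP6 by 2.12 ± 0.06, while ETV4 fell by 1.43 ± 0.07 (SE) on the log2 scale.

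Lists of other lineages moved in different directions. In those called downward, many members had too few counts for the test. These were 8 of 14 for definitive endoderm, 9 of 16 for neural ectoderm, 8 of 14 for surface ectoderm, amnion and trophoblast, and 5 of 10 for primordial germ cells. A fall could be called only for members with reads at day 0, so these calls say nothing of members low at both stages. Definitive endoderm genes fell in 4 of 6 tested members and rose in 2 (camera adjusted p = 0.011, but adjusted p = 0.176 with an estimated correlation and 0.421 without day 4 replicate 1). AFP was 1773-fold lower (606 to 8599), HHEX fell by 4.51 ± 0.52 (SE) on the log2 scale, and the chemokine receptor CXCR4 rose 88.7-fold to 299.8 ± 79.5 CPM. SOX17 had 0, 1 and 3 counts at day 0 and 2, 0 and 1 at day 4, and FOXA2 had 6, 4 and 4 and then 0, 3 and 0, so neither was tested. Node and notochord genes rose in 4 of 5 tested members and fell in 1 (camera adjusted p = 0.0256, but adjusted p = 0.128 with an estimated correlation). The BMP antagonists NOG and CHRD rose by 5.92 ± 0.53 and 4.24 ± 0.20 (SE) on the log2 scale, and NOG, with 4 counts at day 0, rose by 9.46 without day 0 replicate 3. Neural ectoderm genes fell in 6 of 7 tested members and did not pass in 1 (camera adjusted p = 1.4e-05, but adjusted p = 0.0783 with an estimated correlation). That list includes SOX2, SOX3, which fell by 3.94 ± 0.17 (SE) on the log2 scale, and PAX6, which fell from 1.56 ± 0.211 to 0.674 ± 0.128 CPM.

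Surface ectoderm, amnion and trophoblast genes fell in 5 of 6 tested members and rose in 1 (camera adjusted p = 0.00043, but adjusted p = 0.114 with an estimated correlation). TFAP2C fell by 8.06 ± 0.14 and GRHL2, an epithelial factor, by 5.48 ± 0.14 (SE) on the log2 scale. KRT5 was at least 41.7-fold higher, at 1.66 ± 1.15 CPM, with 88 of its 132 day 4 counts in replicate 1. Its fitted log2 fold change, which is no bound, was 8.36, or 7.52 without day 4 replicate 1. Primordial germ cell genes fell in 4 of 5 tested members and rose in 1 (camera adjusted p = 0.0204, but adjusted p = 0.128 with an estimated correlation and 0.0872 without day 4 replicate 1). DPPA3 was 51.7-fold lower (13.9 to 433), and PRDM1 rose by 2.33 ± 0.22 (SE) on the log2 scale. Blood and endothelium genes were split, with 6 of 11 higher and 5 lower (camera adjusted p = 0.696), a median log2 fold change of 0.91 and a mean of -0.78. LMO2 rose by 4.85 ± 0.15 (SE) on the log2 scale, and KDR, the VEGF receptor, fell from 114 ± 6 to 1.14 ± 1 CPM, a log2 fold change of -6.68 that was -6.08 without day 4 replicate 1 and -7.73 without day 4 replicate 3. Fibroblast genes rose in 6 of 9 tested members and fell in 3 (camera adjusted p = 0.00242, but adjusted p = 0.0783 with an estimated correlation). COL3A1 rose by 5.01 ± 0.12 and PDGFRB by 2.98 ± 0.06, while the contractile gene TAGLN fell by 3.19 ± 0.09 (SE) on the log2 scale.

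Epithelial junction genes fell while most mesenchymal transition genes rose. Of 16 epithelial members 13 fell and 3 rose (camera adjusted p = 2.1e-13, but adjusted p = 0.0616 with an estimated correlation). CDH1, E-cadherin, fell from 260.5 ± 12.6 to 1.23 ± 0.718 CPM, EPCAM fell by 7.23 ± 0.10 (SE) on the log2 scale, and CRB3, a polarity protein, was at least 247-fold lower. The 3 that rose were the keratins KRT8, KRT18 and KRT19, of which KRT19 rose most, by 1.63 ± 0.10 (SE), and they were named after their values were seen. The epithelial list median of day 4 replicate 1 deviated by -0.405 from the other day 4 libraries. Mesenchymal transition genes rose in 9 of 13 tested members, fell in 3 and did not pass in 1 (camera adjusted p = 9.9e-07, and adjusted p = 0.0446 with an estimated correlation). CDH11 rose 85.3-fold to 1355 ± 30.6 CPM, SNAI1, a repressor of CDH1, 47.6-fold to 80.8 ± 1.81 CPM, and ZEB2 22.9-fold. CDH2, N-cadherin, fell 1.53-fold, from 417 ± 10.2 to 273 ± 18.8 CPM.

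Cell cycle lists held members that rose and members that fell. Mitotic genes rose in 7 of 20, fell in 9 and did not pass in 4, and adjusted over the list alone 8 rose and 10 fell (camera adjusted p = 0.888, and 0.00636 downward by fry). TOP2A rose by 0.65 ± 0.06 and UBE2C fell by 0.80 ± 0.05 (SE) on the log2 scale. DNA replication genes rose in 5 of 20, fell in 10 and did not pass in 5 (camera adjusted p = 0.994). MCM5 fell by 1.43 ± 0.08 and UHRF1 rose by 1.28 ± 0.12 (SE) on the log2 scale, and day 4 replicate 1 deviated by 0.254 in this list. Targets of p53 fell in 11 of 14, rose in 0 and did not pass in 3 (camera adjusted p = 0.0043, but adjusted p = 0.145 with an estimated correlation). MDM2, the ligase that degrades p53, fell 4.41-fold from 459 ± 9.82 to 104 ± 7 CPM, and PHLDA3 fell 8.49-fold. CDKN1A, the p21 inhibitor, did not pass (58.7 ± 1.24 and 64.5 ± 6.4 CPM, adjusted p = 0.13), and over the alternatives its adjusted p ran from 0.00114, without day 4 replicate 1, to 0.411, and passed also with upper quartile factors (0.034).

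Cholesterol synthesis genes rose in 19 of 20 members, fell in 0 and did not pass in 1 (camera adjusted p = 7.4e-07, but adjusted p = 0.176 with an estimated correlation). INSIG1 rose 8.13-fold, from 36.5 ± 0.839 to 296.5 ± 22.8 CPM, MVK 3.85-fold and HMGCS1 2.97-fold, and the list median was 1.06 on the log2 scale. Glycolysis and hypoxia genes were mixed, with 11 of 20 higher, 6 lower and 3 not passing (camera adjusted p = 0.395). PDK1 rose by 2.36 ± 0.11, while the glucose transporter SLC2A1 fell by 2.28 ± 0.21 (SE) on the log2 scale. Transcripts of the mitochondrial genome for oxidative phosphorylation rose in 1 of 13, fell in 3 and did not pass in 9, and adjusted over the list alone 0 rose and 3 fell (camera adjusted p = 0.899). MT-ND3 fell by 0.52 ± 0.08 (SE) on the log2 scale. The member that rose was MT-ND2, from 12.9 ± 1.95 to 18 ± 4.52 CPM (adjusted p = 0.0298), which 3 of 15 alternatives did not call (0.000128 to 0.132, highest without day 0 replicate 2). Mitochondrial ribosomal RNA took 0.492% to 0.681% of counts at day 0 and 1.04%, 2.47% and 0.708% at day 4. Immediate early and heat shock genes rose in 3 of 11, fell in 5 and did not pass in 3 (camera adjusted p = 0.907), with a median of -0.02 and a mean of 0.36. JUNB rose by 1.47 ± 0.11 and JUN fell by 1.70 ± 0.07 (SE) on the log2 scale.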

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

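The removal of structural RNA genes was chosen after seeing the data, and all other alternatives were listed before. The count of changed genes ran from 11781 (filter of at least 1 CPM) to 15091 (no filter), and that of genes changed by more than 2-fold from 4260 (DESeq2) to 6237 (no filter), against 12928 and 5096. Leaving out each library gave 12260 to 14172 and 4942 to 5593, both highest without day 4 replicate 1. Same-numbered libraries had correlations of deviations of 0.0336, 0.0135 and 0.0183, against -0.0328 to 0.0232 for libraries with different numbers. No strong pairing by replicate number was seen, but such small values cannot show that the samples were unpaired. With the replicate number as a block, the counts were 12809 and 5075. Under that block the adjusted p was 0.056 for definitive endoderm and 0.0387 for retinoic acid. Of 147 named genes tested, 1 (MT-ND2) lost its call in some alternative, 17 gained one and 4 turned direction. Of the genes that gained a call, 12 did so without day 4 replicate 1. The cause of the differences below was not tested.

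The number of lists called was 14 with limma-voom, 6 with a correlation estimated per list, 27 with fry and 20 to 21 with a library left out. Limma-voom gave adjusted p-values above 0.05 for definitive endoderm (0.293), node and notochord (0.141), surface ectoderm (0.0585), fibroblasts (0.101), germ cells (0.132), BMP (0.141) and Notch (0.084). With an estimated correlation those lists gave 0.176, 0.128, 0.114, 0.0783, 0.128, 0.128 and 0.516. The others lost there were presomitic (0.118), lateral plate (0.118), neural (0.0783), Nodal (0.0543), HOX 5 to 9 (0.0543), epithelial (0.0616), p53 (0.145) and cholesterol (0.176). Fry, which asks whether a list moves on balance without comparing it with other genes, called intermediate mesoderm (0.00582), blood (0.00434), FGF (0.000525), retinoic acid (0.00235), mitosis (0.00636) and glycolysis (0.00801).

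Lists that changed direction had no call with camera in either direction. DNA replication turned upward with library size only (0.976), upper quartile factors (0.944), the stricter filter (0.954) and structural RNA removed (0.997). Immediate early genes turned downward with limma-voom (0.832) and fry (0.887). With a library left out, adjusted p-values ran from 0.58 to 0.994 for DNA replication, 0.673 to 0.823 for blood (downward without day 4 replicate 1 or 3, against upward with fry), 0.673 to 0.909 for mitochondrial transcripts, 0.00627 to 0.421 for definitive endoderm, 0.0142 to 0.0872 for germ cells and 0.00822 to 0.256 for retinoic acid. The highest values for endoderm and germ cells, and the lowest for retinoic acid, came without day 4 replicate 1.

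Named genes that changed direction were DDIT3 (log2 fold change 0.0284 with library size only and 0.0638 with upper quartile factors), MCM2 (-0.0045 with DESeq2) and TLX2 (-0.0347 with limma-voom). With a library left out, log2 fold changes ran from -0.11 to 0.17 for DDIT3, -0.0048 to 0.15 for DNAJB1, -0.0815 to 0.1025 for MCM2 and -0.16 to 0.35 for TLX2. Leaving out 1 library moved the fitted fold of 29 called named genes by over 1.5 times, 24 of them with at most 10 counts in all in their lower group. Depth limits such genes, and counting intervals are given for those with 1 to 3 counts that the report describes.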

Other observations

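Further gene families were looked at after the gene lists, 12 in all, and were chosen after seeing the data. All 9 tested metallothionein genes, which bind zinc and copper, fell, with a median log2 fold change of -5.72 (camera adjusted p = 2.5e-10, but adjusted p = 0.194 with an estimated correlation). MT1G fell from 33.4 ± 1.45 to 0.0816 ± 0.0368 CPM, and MT1X from 50.1 ± 0.73 to 5.15 ± 0.955 CPM (SD, n = 3). These genes are near-identical copies that can share reads. Histone genes rose in 48 of 60 tested, fell in 6 and did not pass in 6 (camera adjusted p = 4.7e-05, but adjusted p = 0.552 with an estimated correlation). HIST1H1C rose 2.85-fold and HIST1H1E 2.3-fold. The histone median was 0.735 on the log2 scale, and other RNAs without poly(A) tails were also higher at day 4, with log2 fold changes of 1.10 for RMRP, 1.003 for RPPH1, 1.77 for RN7SK and 0.90 for RN7SL1. Laminin chains rose in 2 of 11, fell in 7 and did not pass in 2, without a call for the family (camera adjusted p = 0.0563). LAMB3 and LAMA3 fell, with log2 fold changes of -6.51 and -5.15, while LAMB1 and LAMA1 rose by 2.29 and 1.97. Of 7 DNA methyltransferases and TET enzymes 5 fell and 2 rose (camera adjusted p = 0.0201, but adjusted p = 0.268 with an estimated correlation). DNMT3B fell from 3490 ± 75.4 to 160.5 ± 2.79 CPM, and TET2 rose by 1.11 on the log2 scale.

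FGF genes, taken by symbol, changed in 14 of 14 tested members, 7 upward and 7 downward (camera adjusted p = 0.255). These include FGF12, FGF13 and FGF14, which are intracellular factors and not secreted ligands. All of them fell, with log2 fold changes of -3.49, -2.38 and -1.97, so the even split is not one of ligands. FGF2 fell from 769 ± 24.2 to 30.3 ± 1.26 CPM, while FGF19 rose from 5.8 ± 0.565 to 99.3 ± 15.4 and FGF10 from 0.534 ± 0.103 to 39.3 ± 8.56. Among Frizzled receptors, 6 of 10 rose and 4 fell (camera adjusted p = 0.186), with a median log2 fold change of 0.50 although the test pointed downward. FZD5 fell from 236 ± 2.73 to 1.25 ± 0.121 CPM and FZD7 from 862 ± 29.5 to 100.3 ± 7.25, while FZD2 rose from 3.15 ± 0.451 to 25 ± 2.62. Wnt ligands rose in 6 of 12, fell in 5 and did not pass in 1 (camera adjusted p = 0.11), with WNT5B rising from 2.86 ± 0.178 to 413 ± 66 CPM. The imprinted neighbours IGF2 and H19 rose by 7.67 ± 0.57 and 9.07 ± 0.60 (SE) on the log2 scale. Their day 4 levels were 53.7, 186 and 122 CPM for IGF2 and 64.2, 188 and 181 CPM for H19, lowest in replicate 1 for both. Eph receptors, collagens, ribosomal proteins, integrins and keratins gave no call (camera adjusted p = 0.361, 0.242, 0.715, 0.0837 and 0.116).

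For the patterns below, tests of POU5F1, of ribosomal RNA and of undifferentiated cells were chosen after the result was seen, and the tests of the path position, of neighbouring genes and of other splits were set before it. POU5F1, a marker of pluripotent cells, had only 4 counts in 6 libraries. Between ZFP57 and KIFC1, the major histocompatibility complex region, 106 of 145 protein-coding genes (73.1%) had under 10 counts, against 17.1% of 18195 others, and their deposited length was a median of 5 times the length of 1 annotated copy, against 0.88. A candidate explanation is that the annotation listed these symbols on several alternative copies of the region, so that their reads were lost at counting. RPS18, a ribosomal protein gene in the region, had 3 counts, 0.0038% of the median of other ribosomal protein genes, so the floor is not particular to POU5F1 and whether its RNA was low cannot be told from this table. HSPA1A, with 0 counts, and HSPA1B of the heat shock list lie in the same region.

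Day 4 replicate 1 differed from the other day 4 libraries, with a median deviation of 0.543 in the presomitic list and -0.617 in the lateral plate list, and near 0 in the HOX lists (-0.053 and -0.0279). Residual ribosomal RNA could not be the whole cause, since replicate 2 had the highest 28S share while its presomitic median lay 0.105 from that of replicate 3, against 0.543 for replicate 1. For remaining undifferentiated cells, the 20 most abundant day 0 genes that fell over 100-fold had a median deviation of -0.269 with quartiles of -0.794 and 0.135. Only 6 of the 20 were higher than in the other day 4 libraries, and a median below 0 was the outcome set against this explanation. The quartiles lie on both sides of 0, so a part of such cells in the difference is not settled. A count added after this result, that 0 of the 7 presomitic genes higher in replicate 1 had a day 0 level above that of the other day 4 libraries, was fixed by their rise by day 4 and decides nothing. An earlier position on the path from day 0 to day 4 was tested by the slope of the deviation on fold change. That slope was 0.000999 (95% bootstrap interval over genes -0.00302 to 0.0048). It lies above 0, the outcome set against this explanation, and the interval does not reach the -0.02 set for it. The interval also spans 0 and genes are not independent, so the path position is not fully settled. Other biological explanations were not tested, as the labels give the day 4 libraries no further grouping.

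Genes next to strongly rising genes tended to rise. The nearest tested neighbours of the 100 most risen genes had a median log2 fold change of 6.6. It was 1.85 without HOX genes and a few genes near them picked by name, or 1.4 without these and overlapping pairs. Other genes in or beside the HOX clusters were not removed. The 95% range of random sets ended at 0.234, 0.219 and 0.194 (permutation test, 1-sided p = 0.0001 for each of the medians, the smallest that 10000 sets can give). Over the 58, 78 and 83 neighbours not themselves among the 100 genes, the medians were 1.32, 0.872 and 0.964, where the 95% range of random sets ended at 0.282, 0.233 and 0.209. Examples chosen after their values were seen are FENDRR next to FOXF1 (8.34), SLC6A7 next to CDX1 (5.57) and MYO3B next to SP5 (5.22). A candidate explanation is activity shared between neighbouring genes, while transcripts that run past annotated ends could give the same values and were not tested, nor were random sets matched on expression.

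The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 12928 changed genes and 5096 changed by more than 2-fold, and the highest of the other splits gave 0 and 0. For gene lists the real split gave 21 and the highest other 15, or 6 and 0 with an estimated correlation. In each case 1 split, the real one, gave as many. The other splits mix the stages unequally and place most of the stage difference within the groups, so their counts are no chance level.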
